A study of Homo sapiens with 7 samples.

How the data were processed

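Gene expression was measured by RNA sequencing in 7 libraries from MCF7 cells, an estrogen receptor positive human breast cancer line. 4 libraries came from cells carrying a vector for a control hairpin against luciferase (shLuc 1 to 4), and 3 from cells carrying a vector for a hairpin against the long noncoding RNA lncRNA-HAL (shlnc-HAL 1 to 3). Per the labels' protocols, the transfections were stable, cells were selected with 0.7 µg/mL puromycin, RNA was isolated with Trizol, and libraries were made with a stranded total RNA kit and sequenced as paired reads of 76 bases. The labels do not say whether libraries of a group came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical. No sequencing batch or date is given in the sources used here.

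Per the submitters' processing notes, reads were processed with Trimmomatic 0.33, STAR 2.4.2 and RSEM 1.2.29 on GRCh38. The deposited table, per its file header a normalized matrix of RSEM gene results, holds 60725 genes in the 7 libraries and 0 columns that belong to no sample. The deposited values are a signal on a linear scale, namely RSEM expected counts divided by 1 size factor per library. This was read from the values: in each library the most common nonzero value, the value of 1 read, was taken as a step. All nonzero values below 100000 steps were multiples of 0.01 of that step. Between 81.6% and 83.4% of nonzero values were whole multiples of the step at a tolerance of 0.001, so expected counts rather than whole reads were recovered. The size factors implied by the steps equalled the median-of-ratios size factors computed from the recovered expected counts over the 18710 genes above 0 in all 7 libraries. The authors' scaling method is not given in the sources used here. Multiplying back gave 18621509 expected counts in shlnc-HAL 3, the shallowest library, and 27114795 in shLuc 2, the deepest.

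Gene types and coordinates were taken from GENCODE release 29 on GRCh38 by gene identifier, without version. It held 57055 of the 60725 genes (94.0%), and the remaining genes took 0.0851% to 0.101% of the summed values per library. Whether strand was used in counting is not given in the sources used here, so a gene and its antisense partner may share reads. Genes with near-identical copies, among them histones, ribosomal protein genes and mitochondrial genes with nuclear copies, are also uncertain, because a read can match several copies.

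Genes with a deposited value of at least 10 in at least 3 libraries were tested, which left 16216. Values were analysed as log2(value + 1), so fold changes are on that scale and understate the change of low genes. The comparison was shlnc-HAL minus shLuc, with limma 3.58.1 (linear model, empirical Bayes with trend, two-sided) in R 4.3.3 and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. 28 gene lists had been fixed before the data were examined. They covered G1/S and replication, G2/M and mitosis, replication histones, growth arrest, estrogen-induced, luminal, basal, mesenchymal, epithelial junction and stem cell genes. They further covered hypoxia, interferon, unfolded protein and integrated stress response, p53, NRF2, cholesterol, NF-kappaB, TGF-beta, Notch, Wnt, immediate early and apoptosis genes. The remaining lists held mitochondrial, ribosomal protein and nuclear structural RNA genes, and fibroblast, leukocyte and endothelial markers. The 26 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Shares of summed values and list levels per library were compared by two-sided exact permutation over the 35 splits of 7 libraries into 4 and 3, whose smallest p is 0.0571. Principal components and Pearson correlations were computed on the same log2 values. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 prepared the values and drew the plots.

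The genes named follow a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls among called genes of sufficient level, 2 called members of each list or otherwise the member with the smallest p, and 5 called noncoding genes. If fewer than 16 genes meet the first part it takes up to 10 genes with the smallest p. 0 genes met the first part, so the 10 genes with the smallest p and 1 member of each list were named. Genes outside the rule are said to have been chosen after their values were seen.

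The libraries formed 2 sets in the data that crossed the hairpin groups. Fits with a term for the set, within the 4 libraries of set A, within the 3 libraries of set B and of the difference between sets were added after seeing the data. The sets were tested against each other only as 1 of the 35 splits of the libraries, a count that is no evidence for the sets, since they were defined from the same values. Other settings chosen before the data were examined were other pseudocounts, filters, scalings, empirical Bayes settings, library weights, replicate numbers as a block, and leaving out each library. Count-based tests were planned only if reads could be recovered, and limma's voom on the recovered expected counts was added instead. The fits were tested on simulated data with 200 changed genes, drawn from genes with a mean value of at least 100. All genes of a set had the same dispersion, 0.001 in set A, the lowest the simulation allowed, and 0.0196 in set B. Real genes differ in spread, so the recovered shares given next may be too high for these data. Over all 7 libraries, 62% of genes changed by a factor of 2 and 94% of those changed by a factor of 4 were recovered among 16216 genes. With the set term and within set A, 100% were recovered at both sizes. lncRNA-HAL itself was not analysed here, because the labels give neither an identifier nor coordinates for it. The symbol HAL in the table belongs to the protein-coding histidine ammonia-lyase gene and was not taken for it.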

Results

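Total RNA was profiled from MCF7 cells stably expressing either a luciferase control hairpin (shLuc, 4 libraries) or a hairpin directed at lncRNA-HAL (shlnc-HAL, 3 libraries). The comparison asks which genes differ when this long noncoding RNA is silenced. The labels report a decrease of lncRNA-HAL by quantitative PCR 72 hours after seeding, and the transcript itself was not analysed here. Recovered expected counts were 23731445, 27114795, 21223507 and 26020408 in shLuc 1 to 4 and 24881605, 24861535 and 18621509 in shlnc-HAL 1 to 3. Between 22456 and 25199 genes had a value above 0. The mitochondrial 16S ribosomal RNA gene MT-RNR2, chosen after its values were seen, was the most abundant gene and took 13.4% to 17.1% of the summed values.

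Luminal genes were abundant in all 7 libraries. The genes named in this paragraph were chosen after their values were seen. The estrogen receptor gene ESR1 lay between 5766 and 7215 normalized expected counts, and the luminal keratin gene KRT8 between 30130 and 68230. The libraries nevertheless fell into 2 sets that crossed the hairpin groups, which were defined from the data. Set A held shLuc 2, shLuc 3, shlnc-HAL 1 and shlnc-HAL 2, and set B held shLuc 1, shLuc 4 and shlnc-HAL 3. NEAT1, the architectural RNA of paraspeckles, lay between 60980 and 85160 in the set A libraries and between 4178 and 7677 in those of set B. The nuclear long noncoding RNA KCNQ1OT1 lay at 6526 to 7762 and at 1190 to 2480. This did not hold for all such RNAs, as MALAT1 overlapped, at 52510 to 83450 and at 27920 to 67370. Long noncoding genes together took 2.73% to 3.64% of the summed values in set A and 1.43% to 5.06% in set B. Small spliceosomal and nucleolar RNAs lay the other way from NEAT1. RNU11, of the minor spliceosome, was at 373 to 504 in set A and at 11640 to 18810 in set B, and SNORA53 was at 47.1 to 124 and at 3603 to 4425. Small nuclear and nucleolar RNA genes together took 1.23%, 0.765%, 1.18% and 0.614% of the summed values in shLuc 2, shLuc 3, shlnc-HAL 1 and shlnc-HAL 2. Their share was 5.84%, 7.03% and 6.20% in shLuc 1, shLuc 4 and shlnc-HAL 3. Protein-coding genes took 67.8% to 69.4% in set A and 58.2% to 59.7% in set B. The first principal component held 55.07% of the variance and parted the sets. Across genes, Pearson's r was 0.937 to 0.950 between libraries of different sets and 0.964 to 0.990 within a set, whichever hairpin they carried.

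**Figure D1:**
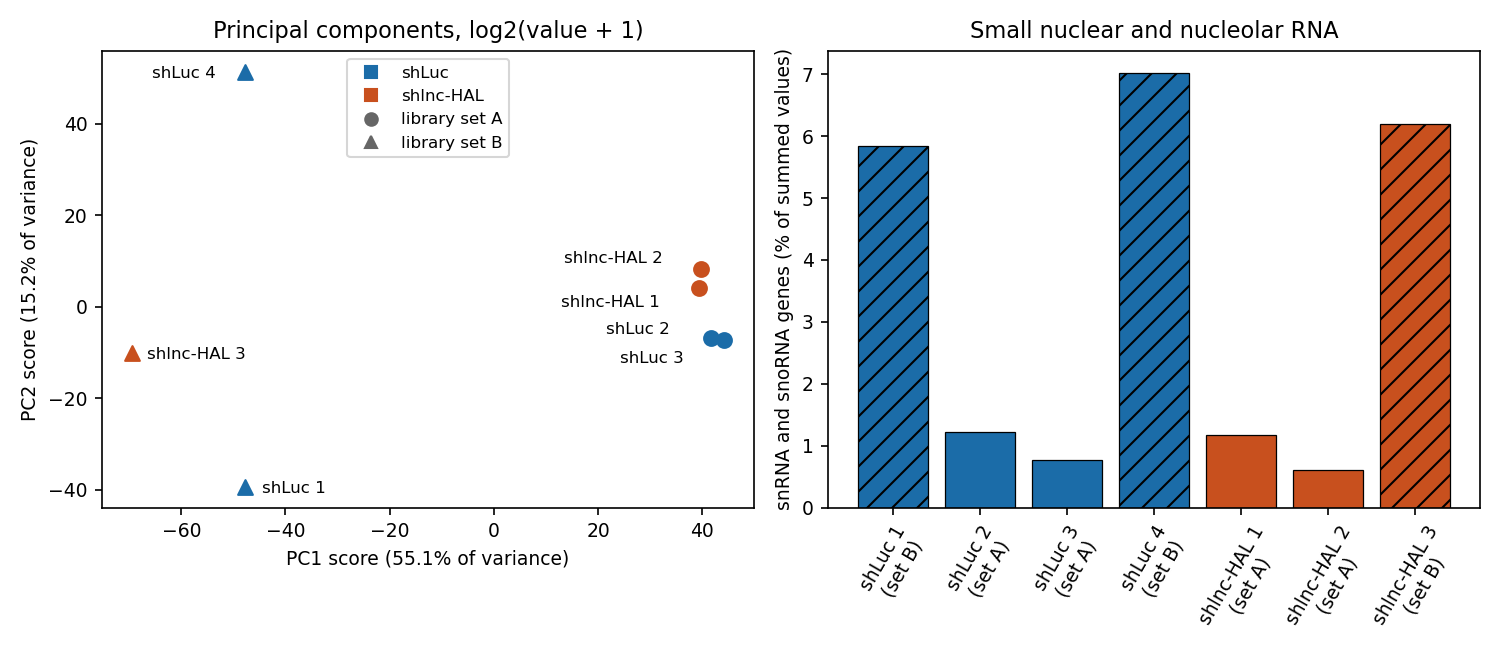
The left panel plots the scores of the 7 libraries on the first 2 principal components of log2(value + 1), and the right panel the share of the summed values in small nuclear and nucleolar RNA genes, in percent, with color for the hairpin and marker shape or hatching for the library set. The 3 set B libraries lie apart on the first component and have shares of 5.84% to 7.03%, against at most 1.23% in the 4 set A libraries.

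The clearest difference between shlnc-HAL and shLuc cells was in BMP5, which encodes a secreted bone morphogenetic protein. BMP5 (chromosome 6, 55753645 to 55875564) had 60.4 ± 17.1 normalized expected counts in shLuc (SD, n = 4) and 6.48 ± 0.801 in shlnc-HAL (n = 3), a log2 fold change of −3.01 ± 0.31 (SE). CYP1B1 (chromosome 2, 38066973 to 38109902), a cytochrome P450 that hydroxylates estradiol, had 2232 ± 267 in shLuc and 4542 ± 145 in shlnc-HAL (log2 fold change 1.03 ± 0.12). AHNAK2 (chromosome 14, 104937244 to 104978357), a large scaffold protein gene, had 1860 ± 55.7 and 1115 ± 141. SLC7A11, the cystine and glutamate exchanger, had 637 ± 76.0 in shLuc and 1013 ± 27.1 in shlnc-HAL. CD44, the hyaluronan receptor, had 229 ± 16.1 and 368 ± 9.83. For these 5 genes no shLuc library overlapped a shlnc-HAL library. None passed the test over all genes, with limma adjusted p values of 0.156 for BMP5, 0.195 for CYP1B1, 0.774 for AHNAK2 and 1.00 for SLC7A11 and CD44.

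The other genes with the smallest p were lower in all shlnc-HAL libraries than in any shLuc library and were not called. PPFIA4, a liprin gene, had 366 ± 62.0 normalized expected counts in shLuc and 196 ± 10.8 in shlnc-HAL. The transcriptional repressor gene KLF12 had 128 ± 24.2 and 48.7 ± 13.6, where shLuc 1 at 164 lay above the other shLuc libraries. The LIM protein gene CRIP2 had 1933 ± 237 and 1249 ± 23.0, and the kinase gene AATK had 215 ± 33.2 and 105 ± 21.5. PSMD5-AS1 (chromosome 9, 120824828 to 120854385), annotated as a transcribed unitary pseudogene, had 362 ± 6.10 and 246 ± 5.00. Its adjusted p in limma was 1.00.

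Over the 7 libraries, limma called 0 of 16216 genes. 586 genes had an unadjusted p under 0.05, 243 higher and 343 lower in shlnc-HAL, where chance gives 811. The groups did not overlap for 910 genes (5.61%), where chance gives 5.71%. With a term for the library set, added after seeing the data, limma called 8 genes, all at an adjusted p of 0.0382. CYP1B1 and the noncoding transcript FLJ20021 rose, with log2 fold changes of 1.02 ± 0.10 and 1.604 ± 0.167 (SE). 6 genes fell. Their log2 fold changes were −2.97 ± 0.27 for BMP5, −1.62 ± 0.17 for the mucin gene MUC5B and −1.19 ± 0.13 for the glycolytic aldolase gene ALDOC. They were −0.79 ± 0.08 for the integrin gene ITGB4, −0.77 ± 0.08 for AHNAK2 and −0.70 ± 0.08 for CERCAM. ITGB4, MUC5B, CERCAM and FLJ20021 were chosen after their values were seen. The libraries of the groups overlapped for MUC5B, CERCAM and FLJ20021. FLJ20021 was at 313.6, 101.5, 70.0 and 359.7 in shLuc 1 to 4 and at 218.7, 240.8 and 1221 in shlnc-HAL 1 to 3. Without shLuc 2, shLuc 3, shlnc-HAL 1 or shlnc-HAL 2 this fit called 0 genes, and without shlnc-HAL 3 it called 7 others. It called 73 genes without shLuc 1 and 163 without shLuc 4, the 8 genes included both times. With voom and the set term, ITGB4, CYP1B1, FLJ20021 and MUC5B were called (voom adjusted p = 0.0463 each). BMP5, AHNAK2, CERCAM and ALDOC were not, at voom adjusted p values of 0.0636, 0.0504, 0.0562 and 0.0636.

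**Figure D2:**
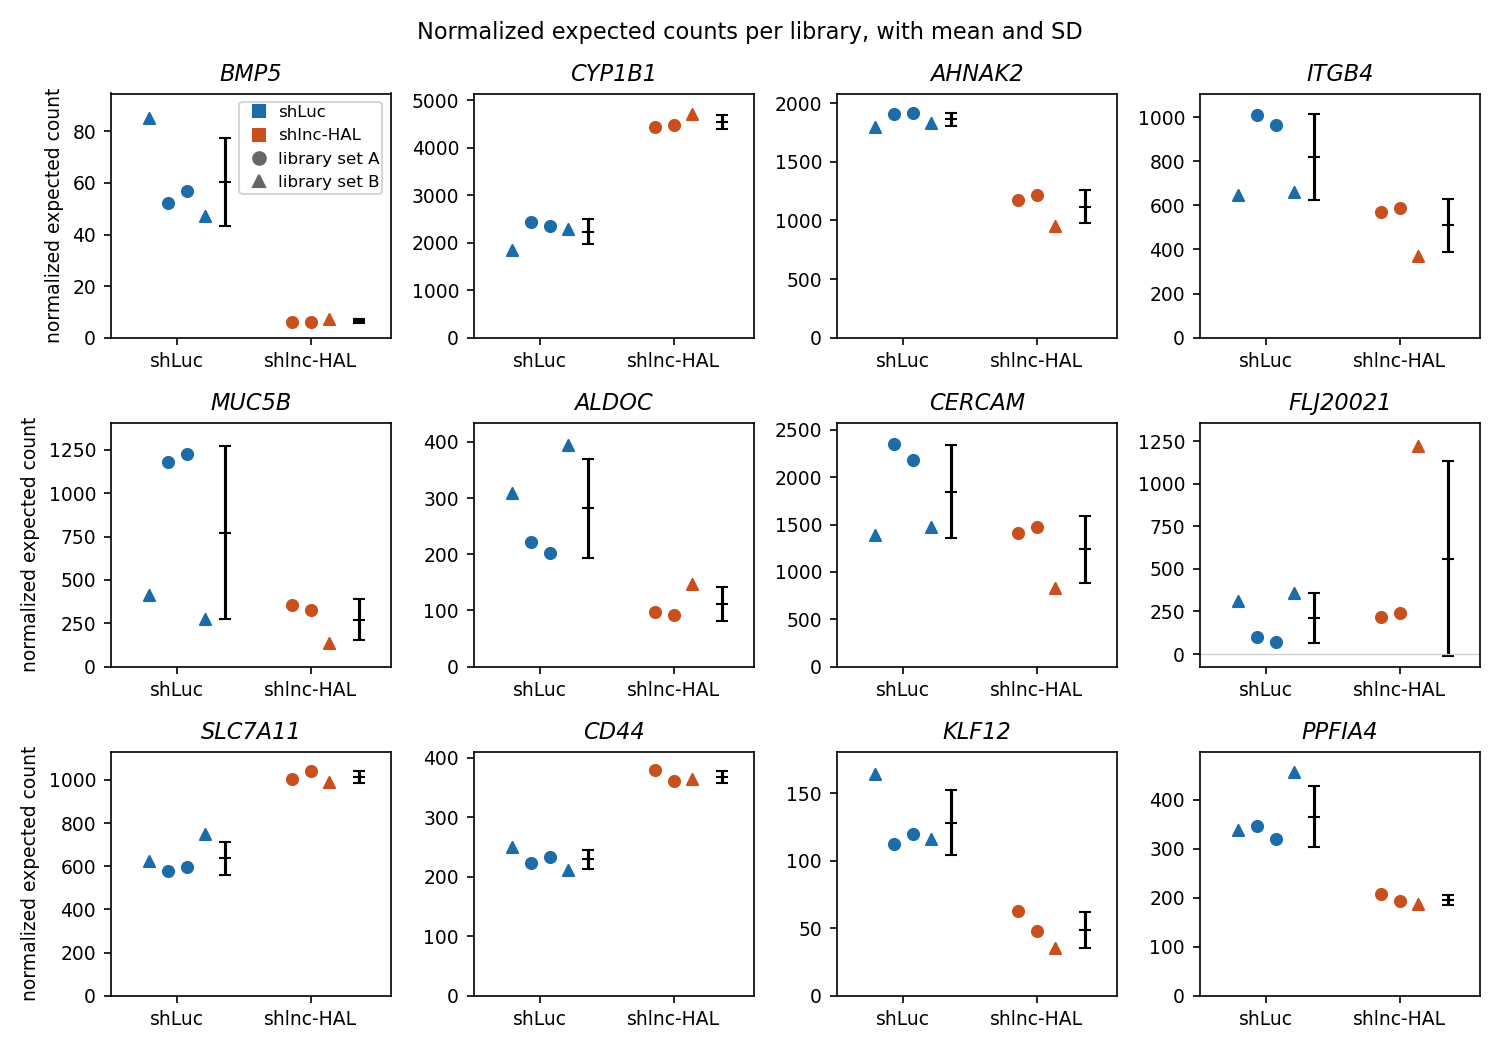
Normalized expected counts of 12 genes on linear axes, with a point per library (blue shLuc, orange shlnc-HAL, circles set A, triangles set B) and the mean and SD of each group in black. BMP5 lies at 47.2 to 85.3 in shLuc and at 5.93 to 7.40 in shlnc-HAL, and CYP1B1 at 1842 to 2439 and at 4446 to 4709.

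Genes of G2/M and mitosis passed as slightly lower in shlnc-HAL cells at a preset correlation between genes, but not with an estimated one. 52 of 55 tested members had a negative log2 fold change, with a mean of −0.18 (camera, preset correlation, adjusted p = 4.03e-12, and adjusted p = 0.121 with an estimated correlation). 0 members were called over all genes, and 0 when adjusted over the list alone. The mean was −0.18 within set A and −0.17 within set B. HMMR, a spindle-associated hyaluronan receptor, had 1268 ± 117 normalized expected counts in shLuc (n = 4) and 970 ± 30.9 in shlnc-HAL (n = 3). KIF18A, a mitotic kinesin, had 551 ± 111 and 342 ± 73.6, and the proliferation marker gene MKI67 had 8811 ± 676 and 7319 ± 1106. KIF18A and MKI67 were chosen after their values were seen. Replication histone genes passed as lower, with a mean of −0.07 and 48 of 63 members negative (camera adjusted p = 0.0116, and adjusted p = 0.446 with an estimated correlation). Their mean was −0.096 within set A and −0.057 within set B. HIST1H3C had 1643 ± 69.5 in shLuc and 1265 ± 116 in shlnc-HAL, with 0 members called over all genes or when adjusted over the list alone. The histone call was lost without shLuc 2, the library with the highest histone level, where the mean was −0.0331 (adjusted p = 0.311). The G1/S and replication list did not pass, with a mean of 0.03 and 30 of 55 members positive. Its mean was −0.11 within set A (camera adjusted p = 5.46e-05, and adjusted p = 0.516 with an estimated correlation) and 0.22 within set B, so the sets went opposite ways. CCNE1, cyclin E1, had 276 ± 22.2 in shLuc and 354 ± 92.1 in shlnc-HAL. The growth arrest list did not pass either (mean 0.02, median −0.04), and its nuclear receptor gene NR2F1 had 9.88 ± 5.26 and 28.7 ± 17.4.

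Targets of p53 passed as higher in shlnc-HAL cells at the preset correlation only. 28 of 30 members had a positive log2 fold change, with a mean of 0.27 (camera adjusted p = 1.18e-11, and adjusted p = 0.121 with an estimated correlation). The mean was 0.23 within set A and 0.33 within set B, where shlnc-HAL 3 is the only shlnc-HAL library. Relative to the mean of the 7 libraries, the list level there was 0.178 in shlnc-HAL 3, −0.315 in shLuc 1 and 0.01 in shLuc 4. The death receptor gene FAS had 65.9 ± 10.8 normalized expected counts in shLuc (n = 4) and 121 ± 3.57 in shlnc-HAL (n = 3). XPC, a nucleotide excision repair gene, had 1600 ± 81.4 and 2030 ± 91.3. PPM1D, a phosphatase gene of p53 feedback, had 3678 ± 301 and 4622 ± 93.3. XPC and PPM1D were chosen after their values were seen. 5 members were higher at an unadjusted p under 0.05 and 0 were called, over all genes or when adjusted over the list alone.

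Both stress response lists passed as higher at the preset correlation only. In the unfolded protein and integrated stress response list 27 of 34 members were positive, with a mean of 0.17 (camera adjusted p = 0.000104, and adjusted p = 0.153 with an estimated correlation). The mean was 0.15 within set A and 0.23 within set B. CHAC1, which degrades glutathione, had 29.4 ± 6.09 normalized expected counts in shLuc (n = 4) and 61.2 ± 14.1 in shlnc-HAL (n = 3), and the transcription factor gene ATF5 had 415 ± 103 and 584 ± 61.8. In the NRF2 list of oxidative stress genes 20 of 26 were positive, with a mean of 0.30 (camera adjusted p = 3.21e-06, and adjusted p = 0.446 with an estimated correlation). The NRF2 mean was 0.14 within set A and 0.66 within set B, and it fell to 0.0962 without shlnc-HAL 3. Relative to the mean of the 7 libraries, its level was 0.576 in shlnc-HAL 3, −0.093 and 0.029 in shlnc-HAL 1 and shlnc-HAL 2, and −0.187 to −0.027 in shLuc. The heme oxygenase gene HMOX1 had 42.3 ± 19.7 in shLuc and 88.9 ± 11 in shlnc-HAL. CHAC1, ATF5 and HMOX1 were chosen after their values were seen. SLC7A11 belongs to both lists and was the 1 member that passed in each when adjusted over the list alone, while 0 passed over all genes. Without shlnc-HAL 3 both list calls were lost. The unfolded protein mean was then 0.122 (adjusted p = 0.0557) and the NRF2 mean 0.0962 (adjusted p = 0.381).

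Stem cell genes passed as higher, with 13 of 16 tested members positive and a mean log2 fold change of 0.36 (camera adjusted p = 0.000617, and adjusted p = 0.121 with an estimated correlation). The mean was 0.37 within set A and 0.39 within set B, where shlnc-HAL 3 is the only shlnc-HAL library. Relative to the mean of the 7 libraries, the list level there was 0.302 in shlnc-HAL 3, −0.262 in shLuc 1 and 0.083 in shLuc 4. CD44 and the drug efflux transporter gene ABCG2 passed when adjusted over the list alone and 0 members passed over all genes. ABCG2, chosen after its values were seen, had 212 ± 68.6 normalized expected counts in shLuc (n = 4) and 442 ± 98.4 in shlnc-HAL (n = 3). SOX2, also chosen so, lay at 304, 32.0, 21.3 and 386 in shLuc 1 to 4 and at 200, 244 and 354 in shlnc-HAL 1 to 3. Breast lineage lists did not pass. The luminal list had a mean of −0.10 with 12 of 22 members negative, and GATA3, a luminal transcription factor gene, had 5859 ± 661 in shLuc and 4490 ± 921 in shlnc-HAL. The luminal mean rested on shlnc-HAL 3 and was −0.00781 without it. The basal list had a mean of −0.13 with 10 of 18 negative, and only CD44 passed when adjusted over that list alone. The mesenchymal list had a mean of 0.03 and a median of −0.05, and the tenascin gene TNC had 5.94 ± 4.92 and 20.7 ± 5.37. The epithelial junction list had a mean of −0.06, and OVOL1, an epithelial transcription factor gene, had 478 ± 24.5 and 357 ± 32.4.

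Targets of hypoxia-inducible factor and glycolysis genes passed as lower, with 26 of 33 members negative and a mean of −0.27 (camera adjusted p = 8.61e-06, and adjusted p = 0.565 with an estimated correlation). ALDOC had 282 ± 87.9 normalized expected counts in shLuc (n = 4) and 112 ± 30.1 in shlnc-HAL (n = 3). ENO2, an enolase gene, had 167 ± 22.8 and 102 ± 3.60. The vasodilator peptide gene ADM lay the other way, at 40.7 ± 22.7 and 118 ± 21.1. ALDOC, ENO2 and ADM passed when adjusted over the list alone and 0 members passed over all genes. ENO2 and ADM were chosen after their values were seen. The mean was −0.24 within set A and −0.06 within set B, and the call was lost without shLuc 4, where the mean was −0.114 (adjusted p = 0.0564). The mean was −0.144 without shlnc-HAL 1, −0.159 without shlnc-HAL 2 and −0.508 without shlnc-HAL 3. Immediate early genes passed as lower, with a mean of −0.20 and 18 of 29 members negative (camera adjusted p = 0.0278, and adjusted p = 0.161 with an estimated correlation). Their mean was −0.26 within set A and −0.11 within set B. EGR3, a zinc finger transcription factor gene that estrogen also induces, had 1379 ± 192 and 696 ± 215 and was the 1 member that passed when adjusted over the list alone. The immediate early call was lost without shLuc 2, shlnc-HAL 2 or shlnc-HAL 3, at means of −0.179, −0.162 and −0.234 and adjusted p values of 0.141, 0.0916 and 0.0557.

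TGF-beta and BMP target genes passed as lower (camera adjusted p = 0.0451, and adjusted p = 0.446 with an estimated correlation), with a median of −0.21 and a mean of −0.05. The mean was 0.05 within set A and 0.04 within set B, both against that direction, and the call was lost within set A (adjusted p = 0.342). Their mean also turned positive without shLuc 1, where it was 0.03 and the call was lost (adjusted p = 0.2), and without shLuc 4, shlnc-HAL 1 or shlnc-HAL 2 (adjusted p values of 0.384, 0.135 and 0.3). It was −0.118, −0.166 and −0.234 without shLuc 2, shLuc 3 and shlnc-HAL 3. The receptor gene TGFBR1 had 1229 ± 175 normalized expected counts in shLuc (n = 4) and 954 ± 89.4 in shlnc-HAL (n = 3). The other signaling lists did not pass. Estrogen-induced genes had a mean of −0.01 and a median of 0.01, and only EGR3 passed when adjusted over that list alone. Cholesterol synthesis genes had a mean of −0.09 with 19 of 30 negative (within set A −0.104, camera adjusted p = 0.00662, and adjusted p = 0.516 with an estimated correlation), and the desaturase gene SCD had 22480 ± 5754 and 12908 ± 2494. Interferon-stimulated genes had a mean of 0.16, which shLuc 1 pulled down, since the mean was 0.957 without that library. It turned negative without shLuc 2, shLuc 3, shLuc 4 or shlnc-HAL 3 (−0.132, −0.0432, −0.161 and −0.142). Within set A, which leaves out shLuc 1, the mean was 0.587 with 14 members called higher and 2 lower (camera adjusted p = 1.32e-09, and adjusted p = 0.516 with an estimated correlation), and within set B it was 0.02. IFI35 had 21.8 ± 28.9 and 34.2 ± 28.1. The NF-kappaB list had a mean of 0.14 and the apoptosis list 0.09. Without shlnc-HAL 3 these means were −0.172 and −0.0117, and without shLuc 1 they were 0.342 and 0.189. The NF-kappaB mean was −0.036 within set A and 0.614 within set B. BIRC3, an inhibitor of apoptosis in both lists, had 134 ± 85.9 in shLuc and 476 ± 406 in shlnc-HAL. It was at 944 in shlnc-HAL 3 and at 258 and 226 in shlnc-HAL 1 and shlnc-HAL 2. The Notch list had a mean of 0.01, and HES1 had 741 ± 147 and 583 ± 17.4. The Wnt list had a mean of −0.01 and a positive camera direction, and CD44 was its 1 member that passed when adjusted over the list alone.

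**Figure D3:**
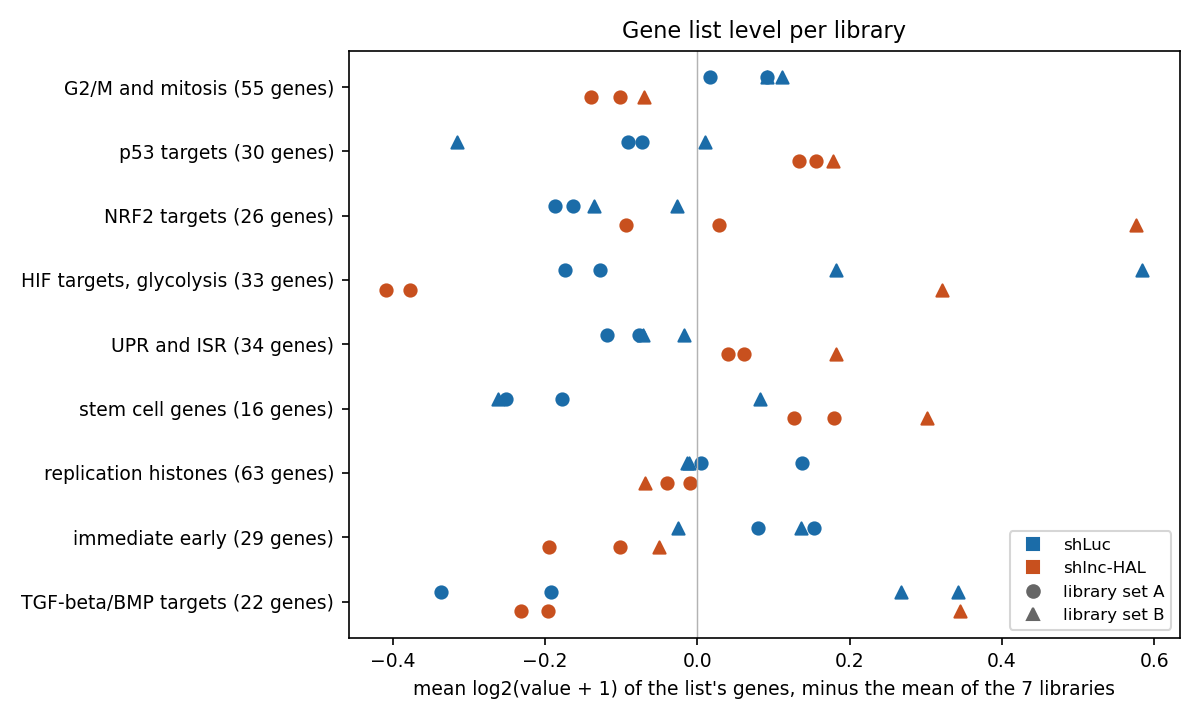
Mean log2(value + 1) of each list's tested genes per library, minus the mean of the 7 libraries, for the 9 lists that passed the camera test, with a point per library (blue shLuc, orange shlnc-HAL, circles set A, triangles set B). The G2/M list lies at 0.017 to 0.111 in shLuc and at −0.14 to −0.07 in shlnc-HAL, and the p53 list at −0.315 to 0.01 and at 0.133 to 0.178.

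Taking each library as 1 value, the levels of 6 of the 28 lists did not overlap between the groups, where chance gives 1.6. These were the G2/M, p53, stem cell, unfolded protein, cholesterol and immediate early lists. The two-sided exact permutation p was 0.0571 for each, the smallest that the 35 splits allow, and 0.267 after Benjamini-Hochberg adjustment over 28 lists.

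The shares of 4 gene classes were compared between the hairpin groups by exact permutation, whose smallest possible p of 0.0571 allows no share to pass 0.05. Mitochondrially encoded genes took 18.3% ± 2.00 of the summed values in shLuc (SD, n = 4) and 18.3% ± 2.45 in shlnc-HAL (n = 3; exact permutation p = 0.971). Ribosomal protein genes took 4.91% ± 0.430 and 4.81% ± 0.0614 (exact permutation p = 0.914). Replication histone genes took 0.882% ± 0.137 and 0.842% ± 0.131 (exact permutation p = 0.743), and nuclear structural RNA genes 8.05% ± 1.62 and 8.04% ± 2.07 (exact permutation p = 0.914). With 4 relations tested, all adjusted p values were 0.971. As lists in the camera test, these 3 groups other than histones did not pass. Mean log2 fold changes were −0.11 for mitochondrial, −0.05 for ribosomal protein and −0.42 for structural RNA genes. Without each library in turn these means ranged from −0.431 to 0.337, −0.187 to 0.0643 and −0.970 to 0.0718, so their signs depend on single libraries. The mitochondrial mean was at 0.337 without shlnc-HAL 3. Ribosomal protein genes passed as higher within set A (mean 0.0457, camera adjusted p = 0.0212, and adjusted p = 0.698 with an estimated correlation), and mitochondrial genes as lower with the set term (camera adjusted p = 0.0272, and adjusted p = 0.828 with an estimated correlation). The mitochondrial mean was 0.067 within set A, against that direction, and −0.736 within set B, where shlnc-HAL 3 is the only shlnc-HAL library. MT-CO2 had 32060 ± 6962 normalized expected counts in shLuc and 28789 ± 10785 in shlnc-HAL, RPL7A had 29874 ± 3510 and 23492 ± 3218, and the telomerase RNA gene TERC had 179 ± 53.7 and 120 ± 40.8. Few markers of other cell types reached the filter: 4 of 14 fibroblast markers, 5 of 16 leukocyte markers and 4 of 12 endothelial markers. Relative to the mean of the 7 libraries, the fibroblast level was 0.962, 0.783 and 0.362 in shLuc 1, shLuc 4 and shlnc-HAL 3. In the set A libraries it was −0.699 to −0.394, so it followed the library sets. COL3A1 of this list, chosen after its values were seen, was at 1134 to 4879 in set B and at 69.99 to 164.4 in set A. S100A4 had 28 ± 12.6 in shLuc and 18.6 ± 3.32 in shlnc-HAL, and FLT1 had 31.4 ± 4.06 and 24.8 ± 8.28. The actin regulator gene CORO1A had 713 ± 208 and 334 ± 77.0 and was the 1 leukocyte marker that passed when adjusted over its list alone, and that list did not pass (mean −0.37).

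Within set A, where both hairpins had 2 libraries, limma called 1649 genes, 735 higher and 914 lower in shlnc-HAL. Genes on the long arm of chromosome 9 were lower as a block. Of 608 tested genes on chromosome 9, 226 (37.2%) were called lower, against 4.41% elsewhere (Fisher's exact test, two-sided, adjusted p = 1.84e-128). This test was planned for genes called over all 7 libraries, of which there were 0, and was moved to set A after seeing the data. It takes genes as independent, which neighbouring genes that shift together are not, so its p values may be too small. The bounds of the segments on chromosomes 9 and 12 were set from the set A differences themselves, so their set A values are descriptive. Over 400 tested genes between 71911510 and 137046203 the mean log2 difference was −0.33 ± 0.42 (SD over genes), and 218 were called lower and 6 higher. Over 127 genes at the end of chromosome 12 (118149801 to 132585188) the mean was 0.25 ± 0.56, with 33 called higher and 2 lower. In set B the same segments had means of −0.07 and −0.01. Over all 7 libraries, the median level of the chromosome 9 segment was higher in shLuc 2 and shLuc 3 (0.254 and 0.237) than in any other library. The block was thus high in these shLuc libraries rather than low in shlnc-HAL alone. Of the genes named above, CERCAM, PSMD5-AS1, TGFBR1 and RPL7A lie in the chromosome 9 segment and were called lower within set A, with log2 differences of −0.649, −0.576, −0.58 and −0.352 there and −0.782, −0.517, −0.069 and −0.237 in set B. TNC also lies there and was called higher. Outside these segments, for example, AATK on chromosome 17 and FLJ20021 on chromosome 4 each lie in a window of 100 neighbouring tested genes beyond the range over shuffled genes. Those windows had means of −0.271 and 0.243 in set A and −0.201 and 0.0714 in set B. Other, overlapping windows that hold these genes lay inside that range. By the same Fisher's exact test, called genes were more frequent than elsewhere on other chromosomes too. Lower calls were so on chromosome 17 (8.74%, adjusted p = 0.000587). Higher calls were so on chromosomes 12 (7.27%, adjusted p = 0.00155), 4 (7.97%, adjusted p = 0.00254), 8 (7.85%, adjusted p = 0.00284), 15 (7.41%, adjusted p = 0.00863) and 10 (6.49%, adjusted p = 0.0461). On several chromosomes called genes were less frequent than elsewhere. Examples are lower calls on chromosome 7 (2.25%, adjusted p = 0.00012) and higher calls on chromosome 1 (2.74%, adjusted p = 0.00126). Set B has 1 shlnc-HAL library, and limma called 0 genes in it with 737 at an unadjusted p under 0.05. Of the 1649 genes, 958 (58.1%) had the same sign in set B. The difference between the sets passed for 11 genes, but its set B side rests on shlnc-HAL 3 alone, with the spread taken from the other groups. S100A14, a calcium-binding protein gene chosen after its values were seen, was among them (adjusted p = 0.0417). It lay at 973, 919, 329 and 327 in shLuc 2, shLuc 3, shlnc-HAL 1 and shlnc-HAL 2 and at 861, 825 and 906 in shLuc 1, shLuc 4 and shlnc-HAL 3. Same-group pairs in set A differed by 1.63 to 1.67 times sampling noise (median chi-square over chance, genes of 100 to 1000 reads in the pair), against 7.71 for shLuc 1 and shLuc 4. Pairs of different hairpins in set A differed by 3.38 to 3.99 times, less than these 2 shLuc libraries of set B did from each other.

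**Figure D4:**
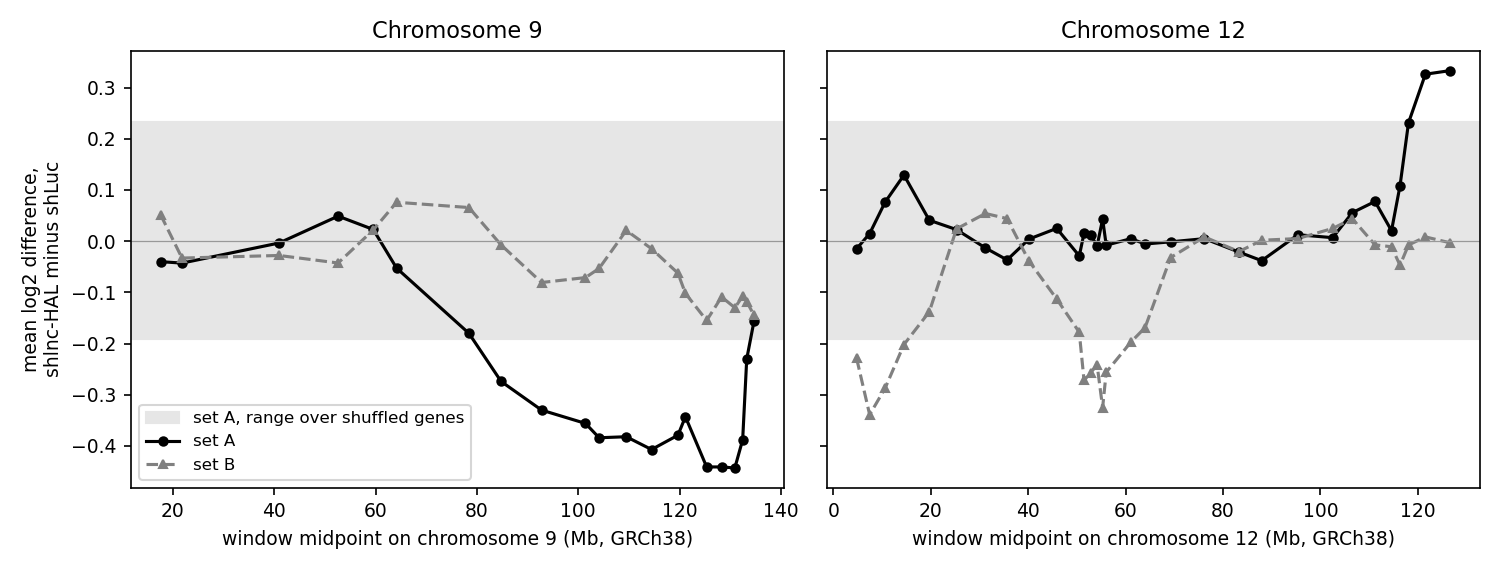
Mean log2 difference (shlnc-HAL minus shLuc) over windows of 100 neighbouring tested genes along chromosomes 9 and 12, against the window midpoint in Mb on GRCh38, within set A (black) and set B (grey), with the range of set A windows over shuffled genes shaded. Set A windows reach −0.44 on chromosome 9 and 0.33 on chromosome 12, and the shaded range runs from −0.19 to 0.23.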

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

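The tests of an offset between library sets, of a wrong label for shLuc 4, of differences between libraries of a group and of list levels over splits were chosen after the results were seen, and so were the fits by library set.

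Among the 4 shLuc libraries, 79 values were checked for a library far from the others, and 6 met the criterion where chance gives about 4. KLF12 was at 164.3 normalized expected counts in shLuc 1, against 119.7 in the nearest shLuc library. IFI35 was at 65.07 in shLuc 1, against 9.13 in the nearest. SCD was at 31040 in shLuc 4, against 20450 in the nearest. The level of the G1/S and replication list was −0.22 in shLuc 4, against 0.037 in the nearest. The replication histone level was 0.137 in shLuc 2, against 0.005 in the nearest. The interferon level was 2.339 in shLuc 1, against −0.662 in the nearest.

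No gene passed the test over all 7 libraries, while 1649 passed within set A. If an offset between the sets were all that hid a shared response, the set A fold changes would recur in set B, and their slope there was 0.127 (95% bootstrap interval over genes 0.0724 to 0.189), below 1. It was 0.316 with shLuc 4 counted as shlnc-HAL, also below 1. As labelled, the set B difference rests on 1 shlnc-HAL library, whose spread this interval does not cover, so an offset together with differences between single libraries stays open. Libraries of a group differing in expression as much as the groups do, with close repeats inside set A, may account for the pattern, since shLuc 1 and shLuc 4 differed by 7.708 times sampling noise, between the 6.979 and 8.607 of the set B pairs of different hairpins. A wrong label on shLuc 4 stays open: putting it with shlnc-HAL gave 30 called genes with the set term against 8, while over the 1649 genes, called without shLuc 4, its position along the set A difference was 0.126, near shlnc-HAL 3 at 0.0847 and apart from shLuc 1 at −0.211, on a scale where 0 is the mean of set B and 1 the full set A difference. As shlnc-HAL 3 lay so close to the mean, these positions do not decide it. Of these genes, 944 (57.2%) lay nearer to the shlnc-HAL than to the shLuc libraries of set A in shLuc 4, against 970 (58.8%) in shlnc-HAL 3 and 822 (49.8%) in shLuc 1, so genes go both ways in every set B library. All 35 splits of the 7 libraries call at least 0 genes by construction, so this comparison says nothing about the count of 0. The highest, 4282 genes, was the split into the 2 sets, a structure of the samples already seen when the sets were defined.

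The 7 libraries formed 2 sets, which no label explains. Removing small, ribosomal and mitochondrial RNA genes left 50.22% of the variance on the first component, and correcting each library for GC content and transcript length left 50.92%, against 55.07% before. Both still parted the same sets, so the parting does not rest on those RNA genes alone or on the corrected trends alone. The removal left 15927 of the 16216 genes, and other shifts in library composition were not tested, nor were both changes together. The sets were defined from these same values, so that they still part decides no technical cause. A difference between library preparations or RNA isolations stays open, as the labels give no batch, and so does a difference in the state of the cells. No biological explanation was tested, because the design names no group that follows the sets.

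Part of the differences within set A lay in chromosome segments, where 218 of the 1649 called genes were lower on the chromosome 9 segment and 33 were higher on that of chromosome 12, and most called genes lay elsewhere. A gain or loss of segments between the cell lines may account for part of them. The most extreme window of 100 neighbouring genes had a mean log2 difference of −0.443, outside the −0.1914 to 0.2323 of shuffled genes. In all, 21 of 564 windows lay outside that range, and neighbouring windows overlap. Of the 21, 6 were on chromosomes other than 9 and 12, with means from −0.271 to 0.243. The median level of the chromosome 9 segment was 0.254 and 0.237 in shLuc 2 and shLuc 3. It was −0.152 to −0.024 in the other 5 libraries, shLuc 1 and shLuc 4 among them. The set A difference thus reflects shLuc 2 and shLuc 3 lying above every other library. Across all 7 libraries the level of this segment did not follow the hairpin, since shLuc 1 and shLuc 4 lay near the shlnc-HAL libraries. Copy number was not measured in these data. An effect of the hairpin on this segment that shows in set A alone was not tested and stays open.

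For the gene lists, 14 of the 35 splits called at least the 9 lists of the real split in the camera test with a preset correlation, and the highest other split called 12, so chance is not excluded for the number of lists. For list levels that did not overlap, 2 of 35 splits gave at least the 6 of the real split, and the other was the split into the 2 sets with 11. With the set term, 2 of 34 splits called at least the 8 genes of the real split, and the other, with 30, put shLuc 4 with the shlnc-HAL libraries. Chance is not excluded for either of these results at a share of 0.05.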

How the results depend on the processing

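The fits with a library set term, within a set and with voom, and the corrected principal components, were chosen after seeing the data. The count of called genes stayed at 0 under other pseudocounts, filters, scalings, empirical Bayes settings and stricter thresholds, with voom, and without each library in turn. The smallest adjusted p ranged from 0.0503 (limma without trend) to 0.629 (without shLuc 3) among these, and the median log2 fold change of all genes was −0.001 in the main fit and −0.001 to 0.024 under other scalings. The exceptions were 1751 genes with estimated library weights (786 higher, 965 lower), which weighted the set A libraries at 1.973 to 8.5 and those of set B at 0.1598 to 0.2903, 8 with the set term, 1649 within set A and 4 with voom and the set term. The weights and set A rest on close repeats, and the causes were not tested further. The set term count ranged from 0 to 163 without each library in turn and was 4 with voom. Of the 26 lists tested, 0 passed camera with an estimated correlation, 0 passed fry for direction, and 4 passed fry for change in either direction. These were the stem cell and p53 lists, which belong to the 9, and the basal and Wnt lists, which do not. The stem cell, basal and Wnt lists share CD44, the member with the smallest p in each, so their results are not independent. The G2/M, p53 and stem cell lists kept their direction and passed camera at the preset correlation under every other fit with at least 2 libraries per group. The TGF-beta list lost its call most often. It failed with a pseudocount of 0.1 (mean −0.007909, adjusted p = 0.0536), without a filter (−0.006081, adjusted p = 0.128), with library weights (0.00437, adjusted p = 0.117), with the set term (0.04646, adjusted p = 0.144), with voom and the set term (0.05821, adjusted p = 0.105) and within set A (0.05054, adjusted p = 0.342). Without each library in turn its mean ranged from −0.2337 to 0.05948, and the call was lost without shLuc 1, shLuc 4, shlnc-HAL 1 or shlnc-HAL 2. The histone list lost its call without a filter (adjusted p = 0.0608). Within set B the hypoxia and histone lists (both adjusted p = 0.739), the immediate early list (adjusted p = 0.564) and the TGF-beta list (adjusted p = 0.463) lost theirs, but set B has 1 shlnc-HAL library, so calls kept or lost there decide nothing. The causes were not tested. 682 of 739 results for named genes kept direction and side of the threshold, 54 passed, and 3 turned direction. These were MT-CO2 with library weights (0.08725) and without shlnc-HAL 3, in a range of −0.4617 to 0.1132 without each library in turn, and NR2F1 within set B (−0.103). The first component held 51.52% and 57.99% of the variance with pseudocounts 0.1 and 10, 61.11% with a minimum of 50, 50.22% without small, ribosomal and mitochondrial RNA genes, 50.92% after GC and length correction, and 54.93% to 61.57% without each library in turn. Group differences in shares, in percentage points, ranged without each library from −1.293 to 1.141 for mitochondrial, −0.2403 to 0.0893 for ribosomal protein, −0.0964 to 0.03545 for histone and −1.162 to 0.8342 for structural RNA genes, so their signs depend on single libraries.

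Whether the replicate numbers pair the libraries could not be told. Deviations from the group means correlated at −0.438, 0.495 and −0.602 for equal title numbers, and at −0.438, 0.536 and 0.451 for the numbers in the descriptions. The positive values came from pairs within a library set and the negative ones from pairs across sets. They follow the sets, so they do not decide a pairing. With these numbers as a replicate block, 0 genes were called both times, and 7 and 10 lists. Under the title block the hypoxia call was lost (adjusted p = 0.0606), and so was the TGF-beta call, with its mean turned to 0.05948 (adjusted p = 0.391). The histone call was lost under the description block (adjusted p = 0.353).

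The 2 planned count-based tests were not run, because only 81.6% to 83.4% of nonzero values came out as whole reads. In simulated data over 7 libraries, 62% of genes changed by a factor of 2 were recovered, which limits what a count of 0 can exclude. The simulation gave all genes of a set the same dispersion, so the share in these data may be lower.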

Other observations

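The genes named here were chosen after their values were seen. Interferon-stimulated genes were high in shLuc 1, at a list level of 2.339 relative to the mean of the 7 libraries. The other shLuc libraries, at −0.929, −0.662 and −1.014, lay below shlnc-HAL 1 to 3 at −0.028, −0.388 and 0.682. IFI6 was at 12400 normalized expected counts in shLuc 1, at 116.4 to 158.5 in the other 3 shLuc libraries and at 855.2, 623.7 and 2566 in shlnc-HAL 1 to 3. IFIT1 was at 3542 in shLuc 1, at 19.52 to 45.09 in the other shLuc libraries and at 199.2, 111.7 and 772.5 in shlnc-HAL 1 to 3. The collagen gene COL3A1, of the fibroblast list, was at 4879, 77.28, 69.99 and 1134 in shLuc 1 to 4 and at 164.4, 129.1 and 1994 in shlnc-HAL 1 to 3. The BMP target gene ID1 was at 1887 and 3662 in shLuc 1 and shLuc 4 and 1998 in shlnc-HAL 3, against 358.1 to 414.5 in the 4 set A libraries.

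Several genes were nearly off in some libraries and abundant in others of the same hairpin. These were chosen after their values were seen. BZRAP1 was at 0, 0, 1.01 and 290.5 in shLuc 1 to 4 and at 584.9, 620.2 and 159.8 in shlnc-HAL 1 to 3. PEG10, an imprinted gene, was at 2070, 251.4, 255.6 and 3.15 and at 11.02, 9.60 and 182. HMCN1 was at 973.9, 241.2, 249.5 and 4.19 and at 27.1, 30.5 and 25.2. CSMD3 was at 89.6, 133.5, 153.2 and 3.15 and at 0.848, 0.872 and 14.8. In these 4 genes shLuc 4 lay nearer to the shlnc-HAL libraries than to the other shLuc libraries. BMP5 and CYP1B1 went the other way, at 47.2 and 2288 in shLuc 4 against 5.93 to 7.40 and 4446 to 4709 in shlnc-HAL, but both were named from a fit that counts shLuc 4 as shLuc, so neither group of genes decides where it belongs.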
